A study of Mus musculus with 15 samples.

How the data were processed

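Gene expression was measured in retinas of mice at postnatal day 30 on an Illumina mouse expression beadchip, with the RNA of the 2 retinas of 1 animal on each array. The 15 arrays fall into 3 groups of 5 mice on a C57BL/6 background. Mice lacking Nrl served as the control, since Nrl is the transcription factor that directs photoreceptor precursors to the rod fate and retinas without it hold cone-like photoreceptors in place of rods. The other groups lacked Nrl together with Cnga3 or together with Cngb3, the subunits of the cone cyclic nucleotide-gated channel. They are called the Cnga3 and the Cngb3 double knockout here. Groups and replicate numbers came from the sample labels, and no sample was left out.

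Per the labels, total RNA was purified from tissue kept in a phenol reagent and labelled with biotin by an Illumina amplification kit. GenomeStudio is named in the submitters' processing notes. Its version, background setting and filters are not given in the sources used here. The deposited table of non-normalized values holds 1 bead-averaged intensity per probe and array on a linear scale. Per the file headers, it also holds a detection p-value (p_value) per probe and array, which the authors' software computed against each array's negative control probes before deposition, in steps of 1 part in 798. The authors' processed table holds log2 values. These were checked against the intensities and equal the log2 of the quantile-normalized signal to within 0.00039, with the same median of 7.255 on every array and no background subtraction. No slide, scan date or batch is given for any array.

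Intensities were processed with limma 3.58.1 in R 4.3.3 by neqc, which corrects the background by a normal-exponential model, adds an offset of 16, normalizes by quantiles and takes log2. The mean and spread of the negative control probes were inferred from the detection p-values. Of 25697 probes, 13077 with a detection p under 0.01 on at least 5 arrays were kept. Gene symbols came from the probe table, which gave 1 symbol for 23978 probes and none for 1719, and no probe had several. The kept probes covered 9097 genes, 2372 of them with more than 1 kept probe. No coordinates are given, since the sources used here name no genome build. Gene order alone, from the reference table of genes, served to find the neighbours of the targeted genes.

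All 3 groups entered 1 linear model with 12 residual degrees of freedom and 4.73 prior degrees of freedom. The contrasts were each double knockout minus the control, and the Cnga3 minus the Cngb3 double knockout. P-values came from limma's moderated test, two-sided, and were adjusted by the method of Benjamini and Hochberg over the kept probes of each contrast. A probe was called at an adjusted p under 0.05. Values are normalized log2 intensities as mean ± SD over 5 arrays, and the error of a log2 fold change is its standard error (SE). Where a probe was detected on no array of a group, its fold was computed against that group's detection limit and is given as "at least". Unadjusted counts use a p under 0.05.

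Genes were named by a rule. It takes every probe of Cnga3, Cngb3 and Nrl, and per comparison the 10 largest rises and 10 largest falls among called probes whose 5 values do not overlap the other 5, with 1 probe per gene. From each gene list it takes up to 4 called members with the lowest p, or 2 members as values where none was called. A few other list members and neighbours of the targeted genes are named beside them and were chosen after their values were seen. The 33 lists covered cone photoreceptor genes, rod photoreceptor genes, outer segment and cilium structure, the retinoid cycle, photoreceptor transcription factors, cGMP and cAMP signalling, calcium handling, endoplasmic reticulum stress and the unfolded protein response, heat shock and cytosolic chaperones, the oxidative stress response and antioxidants. They also covered retinal injury and gliosis genes, microglia and macrophage markers, interferon response with antigen presentation and complement, cell death genes, the photoreceptor and ribbon synapse, and markers of bipolar, amacrine, horizontal, ganglion and Mueller glia cells. The rest were markers of astrocytes and oligodendrocytes, vascular cells and retinal pigment epithelium, genes of lens, cornea and iris, erythrocyte genes, immediate early genes, circadian clock genes, cholesterol synthesis, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, proteasome subunits and sex-linked genes. The last 3 of the families before the sex-linked genes were taken by symbol prefix. Groups, contrasts, tests, lists, thresholds and the alternatives to try were fixed before the data were examined.

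Each list was tested with camera in limma at a preset correlation of 0.01, with the brightest probe of each gene, for the 31 lists with at least 5 measured members, adjusted over those lists. With no change put in, this preset called 5.2 lists on average over 20 reshuffled sets of these arrays' residuals, and 10 at most. Counts of called members, also taken from the brightest probe of each gene, therefore come first. With the correlation estimated from the data, 0 lists passed in any comparison, and the lowest adjusted p was 0.79 and 0.841 against the control and 0.123 between the double knockouts. List scores are the mean over members of the normalized value minus its mean over all 15 arrays.

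The procedure was tested on simulated data made from reshuffled residuals of the 13077 probes, with 200 changed probes in each of 20 runs. It recovered 14.8% of changes of 0.5 on the log2 scale, 74% of changes of 1 and 98.8% of changes of 2. The median number of false calls was 3 and the highest was 45. A list shifted by 0.5 was recovered in 20 of 20 runs with the preset correlation and in 20 of 20 with an estimated correlation. With no change put in, the estimated correlation called 0 lists on average. These runs covered only the comparison of the Cnga3 double knockout with the control. Recovery in 20 of 20 runs need not hold for lists whose members move together more. Between the double knockouts the pigment epithelium list had a median of -1.19 and an estimated correlation of 0.409. With that correlation its list test gave adjusted p = 0.268. A list that does not pass with an estimated correlation is therefore not shown to be unchanged.

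Alternatives tried were other background corrections, median centring, another offset, the authors' processed values, other detection filters, array weights, fits of only the groups compared, the replicate number as a block, the Xist level as a covariate, stricter thresholds, an estimated correlation and the mean of all probes for the list test, and leaving out each library in turn. After seeing the data, 3 were added, namely leaving out the lens-poor control replicates 1 and 3, the lens list mean as a covariate and the pigment epithelium list mean as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision.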

Results

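The 15 arrays compared retinas at postnatal day 30 in mice without Nrl (n = 5), the Cnga3 double knockout (n = 5) and the Cngb3 double knockout (n = 5). Median intensity ran from 136.8 to 171 per array, and 10302 to 13763 probes were detected. Control replicate 3 was the array with 10302 detected probes, and Cnga3 double knockout replicate 2 the one with 13763. Correlations between arrays of a group lay between 0.9263 and 0.9779 in the control, between 0.9401 and 0.9898 in the Cnga3 and between 0.9793 and 0.9857 in the Cngb3 double knockout. The first 3 principal components held 24.4, 18.1 and 13.4% of the variance.

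The probes of the targeted genes show which transcripts the mutations left in the tissue. Cngb3 fell 4.22-fold in the Cngb3 double knockout, to 6.95 ± 0.21 from 9.03 ± 1.1 in the control (log2 fold change -2.08, SE 0.387, adjusted p = 0.0108). In the Cnga3 double knockout its level was 9.04 ± 0.488. The control values of Cngb3 were spread widely, since control replicate 3 had 7.32 and the highest control had 10.05. The 2 Cnga3 probes read 8.58 ± 0.431 and 7.71 ± 0.157 in the control and 8.3 ± 0.358 and 7.57 ± 0.251 in the Cnga3 double knockout. Neither change passed the test, with log2 fold changes of -0.28 (adjusted p = 0.396) and -0.14 (adjusted p = 0.598). Whether these probes lie in the deleted part of Cnga3 is not given in the sources used here. In the Cngb3 double knockout the Cnga3 probes did not pass either (-0.03, adjusted p = 0.943, and -0.32, adjusted p = 0.251). The Nrl probe was detected on 0 of the 15 arrays, with means of 4.46, 4.48 and 4.49.

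The first comparison asks how a cone-like retina responds to loss of the Cnga3 channel subunit. In the Cnga3 double knockout Guca1b, an activator of guanylate cyclase, fell 10.2-fold, to 5.63 ± 0.322 from 8.99 ± 0.724 (log2 fold change -3.35, SE 0.269, adjusted p = 2.22e-06, n = 5 and 5). Pde6b, a catalytic subunit of the rod phosphodiesterase, fell 7-fold, to 7.41 ± 0.369 from 10.22 ± 0.121 (-2.81, SE 0.151, adjusted p = 1.46e-08). Arr3, the cone arrestin, fell 4.8-fold, to 10.86 ± 0.1 from 13.12 ± 0.247 (-2.26, SE 0.126, adjusted p = 1.46e-08), and its other probe fell by 2.18. Drd4, a dopamine receptor of photoreceptors, rose 4.43-fold, to 12.06 ± 0.297 from 9.91 ± 0.375 (2.15, SE 0.175, adjusted p = 2.3e-06). For these 4 genes all 5 double knockout values lay outside the range of the 5 controls.

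**Figure D1:**
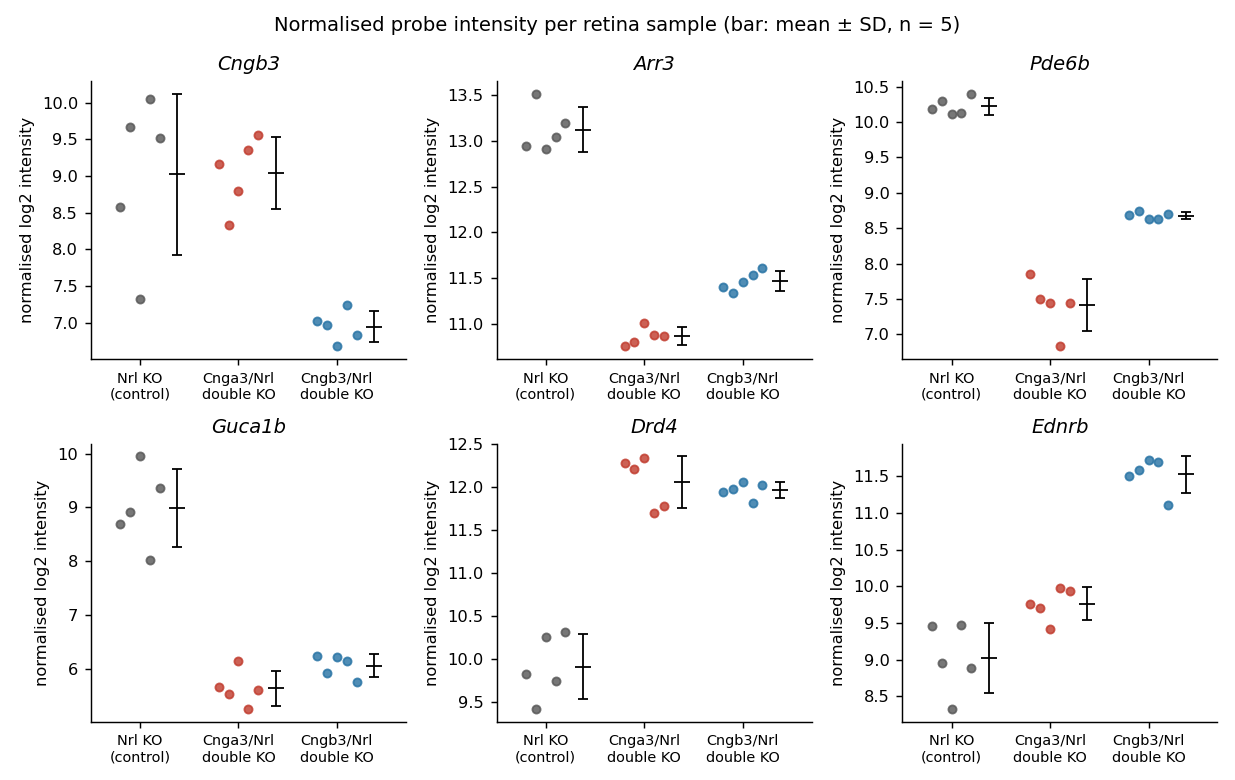
Normalized log2 intensity of Cngb3, Arr3, Pde6b, Guca1b, Drd4 and Ednrb on each of the 15 arrays by group, with bars for mean and SD over 5 arrays. Arr3 averages 13.12 in the control, 10.86 in the Cnga3 and 11.47 in the Cngb3 double knockout, and Cngb3 in control replicate 3 lies at 7.32.

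Other falls in the Cnga3 double knockout included those of Pdzph1 (6-fold, adjusted p = 0.000121), Nme7 (3.33-fold, adjusted p = 0.00374), the histone variant gene H2al1e (3.09-fold, adjusted p = 3.46e-05), Ulk4 (2.91-fold, adjusted p = 0.0162) and Riiad1 (2.84-fold, adjusted p = 3.54e-05). Erdr1 fell 4.5-fold (adjusted p = 0.0254). Of the 4 other probes of Nme7, 1 was called the same way and 2 pointed the opposite way. Other rises included those of the nuclear matrix gene Matr3 (3.35-fold, adjusted p = 0.0178), the interferon regulatory factor Irf7 (2.67-fold, adjusted p = 0.00606), Pdcd4 (2.67-fold, adjusted p = 0.00258), Pcp4 (2.62-fold, adjusted p = 0.0341) and Tspan3 (2.47-fold, adjusted p = 0.00721). Gkap1, which encodes an anchoring protein of the cGMP-dependent kinase, rose 2.51-fold (SE 0.229 on the log2 scale, adjusted p = 0.00355). Pcdh9 was at least 1.74-fold and Gm14325 at least 1.44-fold higher. Rtn1 rose 2.51-fold on 1 probe, while 2 of its 3 other probes pointed the opposite way. The call of Erdr1 ended without control replicate 5 or Cnga3 double knockout replicate 5 (adjusted p of up to 0.0716). That of Pcp4 ended without control replicates 3 or 5 or double knockout replicates 2, 4 or 5 (up to 0.0783).

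Among 16 measured cone photoreceptor genes in the Cnga3 double knockout, 1 rose and 2 fell (3 and 4 adjusted over the list alone). Besides Arr3, the guanylate cyclase activator Guca1a fell by 0.59, and recoverin (Rcvrn) rose by 0.90 on the log2 scale. Among 17 rod photoreceptor genes, 5 rose and 2 fell (7 and 6 adjusted over the list alone). The rises were those of Reep6 (0.72), the rod transducin gene Gnat1 (0.67), the exchanger gene Slc24a1 (0.70), Samd7 (0.82) and Susd3 (at least 1.29-fold). The rod list had a median of 0.14 and a mean of -0.18, so its members moved both ways. Of 24 outer segment and cilium genes, 0 rose and 1 fell, which was the actin-bundling gene Fscn2 (2.73-fold, adjusted p = 0.002; 1 adjusted over the list alone). Of 13 photoreceptor transcription factors, Neurod1 (0.63) and Samd7 rose and 0 fell (2 and 0 adjusted over the list alone). Leaving out 1 library ended the calls of Neurod1 in 7 and of Samd7 in 6 of 10 fits, with adjusted p of up to 0.0788 and 0.0888 without Cnga3 double knockout replicates 5 and 2. The call of Slc24a1 ended without control replicate 2 (0.0784) or double knockout replicates 1, 2 or 3.

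Synapse and calcium genes of the Cnga3 double knockout were mostly higher where they were called. Of 24 genes of the photoreceptor and ribbon synapse, 5 rose and 0 fell (7 and 0 adjusted over the list alone). Dlg4, a scaffold of the photoreceptor terminal, rose by 1.14 (SE 0.226, adjusted p = 0.00787), Rims1 by 0.96, pikachurin (Egflam) by 1.02, Stx3 by 0.78 and Cabp4 by 0.58. The other probe of Egflam and 1 of the 2 other probes of Stx3 pointed the opposite way, and without 1 library the call of Stx3 ended in 5 and that of Cabp4 in 8 of 10 fits (adjusted p of up to 0.0699 and 0.0963, both without control replicate 2). The list passed the preset-correlation test (adjusted p = 0.018), and gave adjusted p = 0.79 with an estimated correlation. It was not called with the pigment epithelium score as a covariate. Cnga3 double knockout replicate 4 had a synapse score of -0.245, where the other replicates had 0.167 to 0.244. That replicate also had the highest pigment epithelium score of its group, at 0.612. Of 28 calcium handling genes, 3 rose and 0 fell (4 and 1 adjusted over the list alone). The list median was -0.0478, so the list as a whole did not rise. Among the tested genes outside the 100 nearest to Cnga3, 9.93% were called on any probe. The 3 of 28 calcium genes are thus near the general share. Called were the plasma membrane calcium pump Atp2b1 (1.09, SE 0.209, adjusted p = 0.00675), the exchanger Slc8a3 (0.99, adjusted p = 0.0124) and the mitochondrial uniporter Mcu (0.84, adjusted p = 0.0179, and 0.0506 without control replicate 2). Of 19 cGMP and cAMP signalling genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone). The phosphodiesterase Pde4b rose by 0.75 (adjusted p = 0.00357) and the adenylate cyclase Adcy1 fell by 1.07 (adjusted p = 0.0106). Pde8a rose by 0.50, and its call ended in 8 of 10 fits without 1 library (up to 0.106 without Cnga3 double knockout replicate 2).

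Of 25 genes of endoplasmic reticulum stress in the Cnga3 double knockout, 3 rose and 0 fell (5 and 0 adjusted over the list alone). The transcription factor Atf4 rose by 0.61 (SE 0.127, adjusted p = 0.00964), Chac1 by 0.83 and Creld2 by 0.47. The list gave adjusted p = 0.0472, and adjusted p = 0.79 with an estimated correlation. Without control replicates 1 and 3 it gave adjusted p = 0.0554. The list score was 0.243 and 0.323 in Cnga3 double knockout replicates 4 and 5, and -0.00985, 0.012 and -0.0797 in replicates 1 to 3, where the controls ran from -0.143 to -0.0134. Of 23 heat shock genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), with Hspa1a up by 0.80 (adjusted p = 0.00448), Hspa4 up by 0.78 and Hsph1 down at -0.74. A dimmer probe of Hspd1, outside these counts, rose by 1.22 (adjusted p = 0.00156). Of 36 oxidative stress genes, Txnrd1 rose (0.80) and Txnip fell by 0.79 (1 and 1 adjusted over the list alone). Of 27 cell death genes, Capn2 rose (0.47) and Parp1 fell by 0.51 (2 and 3 adjusted over the list alone). Of 27 interferon and complement genes, Irf7 alone was called (1 and 0 adjusted over the list alone). Of 24 injury and gliosis genes, Ednrb rose by 0.74 and 0 fell (1 and 0 adjusted over the list alone). Of 24 microglia markers, limma called 0, and 0 passed at an unadjusted p, with Fcrls at -0.42 and Cd14 at -0.44. Calls of Chac1, Creld2, Hsph1, Hspa4, Txnrd1, Capn2, Parp1 and Ednrb ended when some single libraries were left out. The highest adjusted p among them was 0.118, for Creld2 without Cnga3 double knockout replicate 5.

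Cabp5 rose by 0.77 among 19 bipolar markers in the Cnga3 double knockout (1 adjusted over the list alone). Tfap2b rose by 0.57 and Npy fell by 0.46 among 19 amacrine markers (4 and 1 adjusted over the list alone; list adjusted p = 0.0472, and adjusted p = 0.79 with an estimated correlation). Tpm3 rose by 0.67 among 10 horizontal markers (2 and 0 adjusted over the list alone), and Thy1 fell by 0.56 among 17 ganglion cell markers (0 and 1 adjusted over the list alone). Of 20 Mueller glia markers, Car2 (0.52) and Aqp4 (0.70) rose and Trf fell by 0.68 (3 and 1 adjusted over the list alone). Of 8 astrocyte and oligodendrocyte markers limma called 0 (2 at an unadjusted p; Cnp -0.60, Mbp 0.28). Of 16 vascular markers, Flt1 (0.69) and Col4a1 (1.69) rose and Abcc9 fell by 0.73 (2 and 2 adjusted over the list alone). Calls of Cabp5, Tfap2b, Npy, Thy1, Car2, Aqp4, Trf and Col4a1 ended when some single libraries were left out, with adjusted p of up to 0.111 for Aqp4 without Cnga3 double knockout replicate 5. Of the 3 other probes of Tfap2b, 2 pointed the opposite way.

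Of 12 retinal pigment epithelium markers in the Cnga3 double knockout, 0 rose and 2 fell (0 and 8 adjusted over the list alone), with a list median of -0.92. Rdh5 fell by 1.27 and Slc45a2 by 0.62, and the call of Slc45a2 ended in 8 of 10 fits without 1 library (adjusted p of up to 0.099 without control replicate 5). The list gave adjusted p = 0.00654, and adjusted p = 0.79 with an estimated correlation. Without control replicates 1 and 3 its adjusted p was 0.0562. Of 13 retinoid cycle genes, which share Rdh5, Rgr and Rpe65 with that list, Rdh5 alone was called (0 and 3 adjusted over the list alone). Of 24 lens, cornea and iris genes limma called 0 and 11 passed at an unadjusted p (0 adjusted over the list alone). Their median was 2.17 (list adjusted p = 0.00109, and adjusted p = 0.79 with an estimated correlation). Cryaa read 4.28 and 6.6 in control replicates 1 and 3 against at least 12.42 on the other 13 arrays. Without these 2 controls the median of the lens list was 0.09 (adjusted p = 0.847). Of 4 erythrocyte genes, too few for the list test, 0 were called and 0 passed at an unadjusted p (Alas2 -0.47, Hbb-bt -0.38).

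In all, 1051 of 13077 probes were called in the Cnga3 double knockout, 603 higher and 448 lower, for 514 and 395 genes. Median centring in place of quantiles shifted the median of all kept probes by 0.11 and moved the share of called probes that were higher from 57.4 to 83.4%, so the balance of rises and falls depends on the scaling. At least 2-fold changes were 87 rises and 44 falls. Among all tested probes, 6.74% had groups that did not overlap, where chance gives 0.794%. Leaving out control replicate 2 gave 552 calls, Cnga3 double knockout replicate 2 gave 616 and replicate 5 gave 551. Of the 74 called results named for this comparison, 42 stayed past the threshold whichever library was left out.

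The second comparison asks the same for the Cngb3 subunit. In the Cngb3 double knockout Guca1b fell 7.63-fold, to 6.06 ± 0.21 (log2 fold change -2.93, SE 0.269, adjusted p = 1.34e-05). Arr3 fell 3.15-fold, to 11.47 ± 0.106 (-1.65, SE 0.126, adjusted p = 3.98e-06), and Pde6b fell 2.92-fold, to 8.68 ± 0.0524 (-1.55, SE 0.151, adjusted p = 2.66e-05). The endothelin receptor gene Ednrb rose 5.66-fold, to 11.52 ± 0.245 from 9.02 ± 0.477 (2.50, SE 0.201, adjusted p = 4.42e-06), and both of its probes were called. Drd4 rose 4.15-fold, to 11.97 ± 0.0917 (2.05, SE 0.175, adjusted p = 5.67e-06).

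Other rises in the Cngb3 double knockout included Dnaic1, a dynein gene (3.63-fold, SE 0.213 on the log2 scale, adjusted p = 0.000121, both probes), the exchanger gene Slc24a1 (3.56-fold, adjusted p = 4.11e-05) and the nuclear receptor gene Esrrb (2.41-fold, adjusted p = 0.000134). Cox6a2, a subunit gene of cytochrome c oxidase, was at least 3.21-fold higher (adjusted p = 5.36e-05). Miga1 rose 2.75-fold (adjusted p = 0.0108), the transcription factor Trps1 2.53-fold (adjusted p = 0.00385), Chac1 2.46-fold (adjusted p = 0.00713) and Lgr5 2.39-fold (adjusted p = 0.0325). The falls included Ermap (3.35-fold, adjusted p = 4.84e-05), Pdzph1 (3.14-fold, adjusted p = 0.0085), Kash5 (2.59-fold, adjusted p = 0.00389) and Riiad1 (2.58-fold, adjusted p = 0.000102). H2al1e was at least 2.14-fold lower (adjusted p = 5.27e-05), and a probe of Nme7 at least 1.69-fold lower, while 3 of the 4 other Nme7 probes pointed the opposite way. The call of Lgr5 ended in 8 of 10 fits without 1 library, with an adjusted p of up to 0.0804 without Cngb3 double knockout replicate 1.

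Among 16 cone photoreceptor genes in the Cngb3 double knockout, Rcvrn rose by 0.51 and Arr3 and Guca1a fell, the latter by 0.60 (1 and 2 adjusted over the list alone). Among 17 rod photoreceptor genes, Slc24a1, Esrrb and Reep6 (0.61) rose and Guca1b and Pde6b fell (7 and 4 adjusted over the list alone). Fscn2 fell by 1.04 among 24 outer segment genes (2 and 2 adjusted over the list alone). Esrrb rose and Rax fell by 0.76 among 13 photoreceptor transcription factors (3 and 2 adjusted over the list alone). Of 13 retinoid cycle genes limma called 0, with 4 at an unadjusted p (0 adjusted over the list alone; Rbp4 -0.71, Rdh10 0.50). Of 19 cGMP and cAMP genes, Pde8a rose by 0.79 (adjusted p = 0.0108) and 0 fell (2 and 0 adjusted over the list alone). Of 28 calcium genes, Atp2b1 (1.10, adjusted p = 0.0121) and Slc8a3 (1.02, adjusted p = 0.0193) rose and Orai1 fell by 0.62 (2 and 2 adjusted over the list alone). Of 24 synapse genes, Rims1 rose by 0.84 and 0 fell (4 and 0 adjusted over the list alone). The call of Rcvrn ended in all 10 fits without 1 library, and those of Guca1a, Reep6, Fscn2, Rax, Slc8a3, Orai1 and Rims1 in 3 to 8 of 10. The highest adjusted p were 0.132 for Rcvrn and 0.119 for Orai1, both without Cngb3 double knockout replicate 4.

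Of 24 injury and gliosis genes in the Cngb3 double knockout, Ednrb rose and 0 fell (3 and 0 adjusted over the list alone), with a list median of 0.35. The list gave adjusted p = 0.00227, and adjusted p = 0.841 with an estimated correlation. Its scores in the Cngb3 double knockout, from 0.0856 to 0.395, all lay inside the control range of -0.611 to 0.601. Chac1 rose among 25 endoplasmic reticulum stress genes (2 and 0 adjusted over the list alone), and Txnip fell by 0.63 among 36 oxidative stress genes (0 and 1 adjusted over the list alone). Of 23 heat shock genes limma called 0 on the brightest probe of each gene, with 5 at an unadjusted p (1 and 0 adjusted over the list alone; Hspa1a 0.55, adjusted p = 0.0523). A dimmer probe of Hspd1, a member of this list, was called, with a rise of 0.958 (adjusted p = 0.0116). H2-Q7, a class I antigen presentation gene, fell by 1.07 among 27 interferon and complement genes (0 and 1 adjusted over the list alone). Capn2 rose by 0.61 among 27 cell death genes (1 and 0 adjusted over the list alone). Of 24 microglia markers limma called 0 and 3 passed at an unadjusted p (0 adjusted over the list alone; Fcrls -0.81, Fcer1g -0.86). Of 20 Mueller glia markers, Aqp4 (0.98) and Trf (0.79) rose and 0 fell (2 and 0 adjusted over the list alone). Calls of Txnip, H2-Q7, Capn2, Aqp4 and Trf ended when some single libraries were left out, with adjusted p of up to 0.117 for Txnip without Cngb3 double knockout replicate 4.

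Among 19 amacrine markers Npy fell by 0.54 in the Cngb3 double knockout (1 and 2 adjusted over the list alone), and Flt1 rose by 0.63 among 16 vascular markers (3 and 1 adjusted over the list alone). Both calls ended in most fits without 1 library (Npy in 9 of 10, up to 0.106 without Cngb3 double knockout replicate 3, Flt1 in 8 of 10, up to 0.0978 without control replicate 2). In the bipolar, horizontal, ganglion cell and astrocyte and oligodendrocyte lists limma called 0 members, and 7 of 19, 5 of 10, 4 of 17 and 3 of 8 passed at an unadjusted p. Adjusted over the list alone, 1 bipolar marker rose and 3 fell, 3 horizontal markers rose, 0 ganglion cell markers passed, and 2 astrocyte and oligodendrocyte markers rose and 1 fell. Examples were Pcp2 at -0.48, Tpm3 at 0.55, Thy1 at -0.45 and Aldh1l1 at 0.46. Of 12 pigment epithelium markers limma called 0, with 2 at an unadjusted p (1 and 0 adjusted over the list alone; Trpm3 0.62, Ttr 0.82). Of 24 lens, cornea and iris genes it called 0, with 17 at an unadjusted p and 14 higher adjusted over the list alone, among them Lctl (1.95) and Lim2 (2.87). Their median was 2.75 (list adjusted p = 2.11e-07, and adjusted p = 0.841 with an estimated correlation). It was 0.59 without control replicates 1 and 3 (adjusted p = 0.142). With the lens score as a covariate it was 0.05 (adjusted p = 0.827), a fall that follows by construction, since that score is the mean of this list. Of 4 erythrocyte genes 0 were called and 0 passed at an unadjusted p (Alas2 -0.27, Hba-a1 -0.30).

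In all, 351 probes were called in the Cngb3 double knockout, 188 higher and 163 lower, for 169 and 143 genes, with 45 rises and 26 falls of at least 2-fold. Groups did not overlap for 6.69% of all tested probes, where chance gives 0.794%. The count was 828 without control replicate 1, 154 without control replicate 2 and 203 without control replicate 5. It was 130, 138, 171 and 143 without Cngb3 double knockout replicates 1, 2, 3 and 4. Of the 43 called results named for this comparison, 23 stayed past the threshold whichever library was left out.

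**Figure D2:**
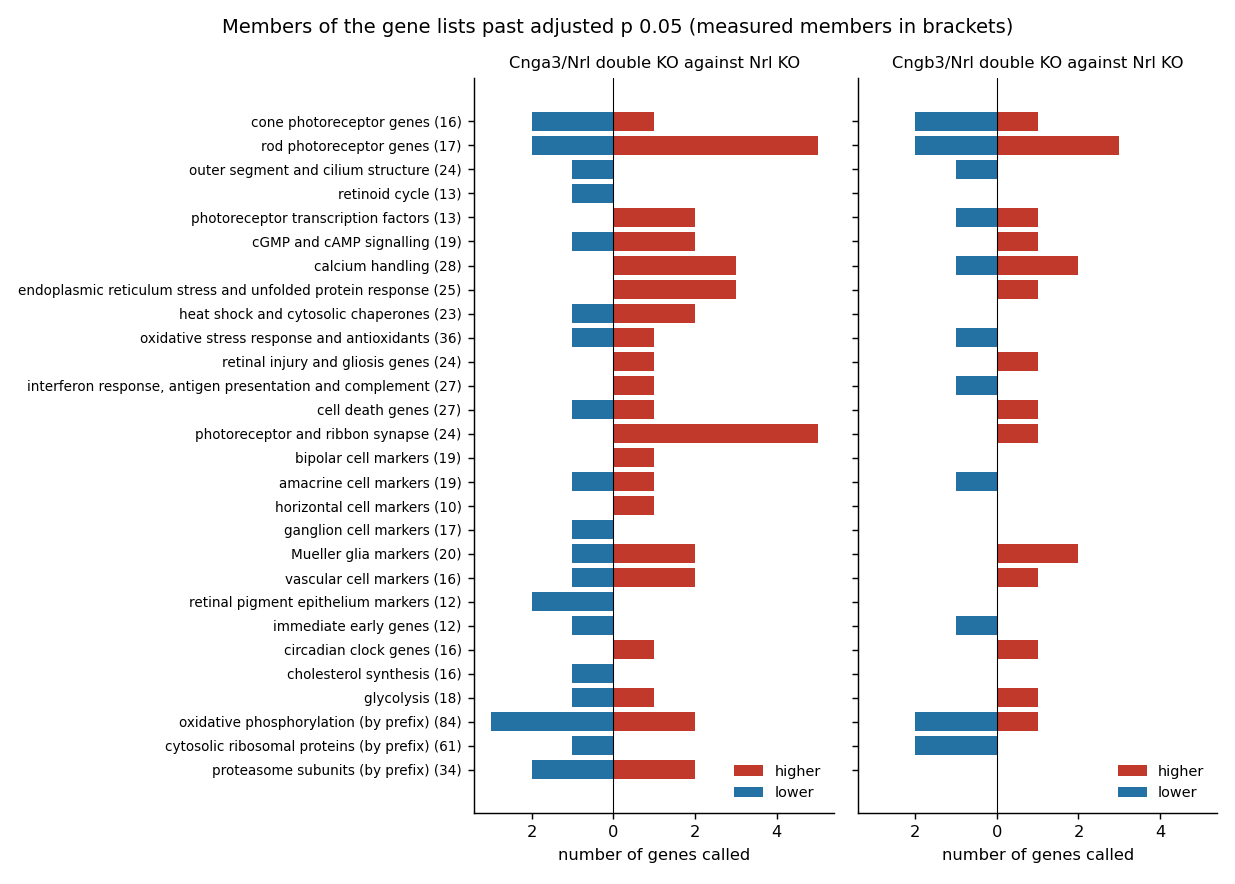
Number of members of each gene list called higher or lower at an adjusted p under 0.05 in each double knockout against the control, with the number of measured members in brackets. The rod list has 5 rises and 2 falls in the Cnga3 and 3 rises and 2 falls in the Cngb3 double knockout.

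The contrast between the double knockouts asks whether loss of either subunit changes the retina in the same way, and the control arrays enter it only through the normalization and the spread. Relative to the Cngb3 double knockout, Pde6b was 2.4-fold lower in the Cnga3 double knockout (log2 difference -1.26, SE 0.151, adjusted p = 0.000569, n = 5 and 5). Esrrb was 3.04-fold lower (-1.60, SE 0.147, adjusted p = 6.51e-05), Ednrb 3.39-fold lower (-1.76, SE 0.201, adjusted p = 0.000374) and Slc24a1 2.19-fold lower (-1.13, SE 0.188, adjusted p = 0.0108). Cabp5, a calcium-binding protein gene of bipolar cells, was 2.39-fold higher, at 10.67 ± 0.297 against 9.41 ± 0.303 (1.26, SE 0.19, adjusted p = 0.00472).

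Further genes lower in the Cnga3 than in the Cngb3 double knockout were Dnaic1 (3.76-fold, adjusted p = 0.000363), Cox6a2 (3.24-fold, adjusted p = 0.00263), the transferrin gene Trf (2.76-fold, adjusted p = 0.00136), the amino acid transporter gene Slc7a3 (2.38-fold, adjusted p = 0.000363), the keratin gene Krt18 (2.24-fold, adjusted p = 0.00136) and Flvcr2 (2.56-fold, adjusted p = 0.0421). Higher were the homeobox gene En2 (2.04-fold, adjusted p = 0.00288), the Notch target Hes5 (2.09-fold, adjusted p = 0.00896), Necab1 (4.48-fold, adjusted p = 0.0257), H2-Q7 (2.57-fold, adjusted p = 0.0246), R3hdm4 (2.14-fold, adjusted p = 0.0227) and Cabp4 (1.91-fold, adjusted p = 0.0245). Cngb3 itself was higher by 2.09 (adjusted p = 0.0251), and the chemokine genes Ccl21a and Ccl21b were at least 1.7-fold and 1.17-fold higher. Of the 24 called results named here, 12 stayed past the threshold whichever library was left out. The others were Cngb3 and Necab1 (adjusted p of up to 0.0933), Ccl21a (0.0845), H2-Q7 and Cabp4 (0.0799), R3hdm4 (0.077), Ccl21b (0.0954), Flvcr2 (0.132), Stra6 (0.138), Rdh5 (0.132), Rgr (0.127) and Ttr (0.119). Each of these was lost in 4 to 7 of 10 fits, mostly without libraries of the Cngb3 double knockout or without Cnga3 double knockout replicates 2, 3 or 5.

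Of 12 pigment epithelium markers, 0 were higher and 3 lower in the Cnga3 than in the Cngb3 double knockout (0 and 6 adjusted over the list alone), with a median of -1.19. These were Ttr (-1.47), Rdh5 (-1.44) and Rgr (-1.66), and the list gave adjusted p = 5.03e-07, and adjusted p = 0.268 with an estimated correlation. Of 13 retinoid cycle genes, Stra6 (-1.34), Rdh5 and Rgr were lower (0 and 4 adjusted over the list alone; list adjusted p = 0.0219, and adjusted p = 0.268 with an estimated correlation). Of 17 rod genes, Esrrb, Pde6b and Slc24a1 were lower and 0 higher (3 higher and 4 lower adjusted over the list alone). Cabp5 among 19 bipolar markers (1 and 0 adjusted over the list alone; list adjusted p = 0.0108, and adjusted p = 0.123 with an estimated correlation) and Cabp4 among 24 synapse genes (1 and 0; list adjusted p = 0.0232, and adjusted p = 0.554 with an estimated correlation) were higher. The injury and gliosis list was lower, with Ednrb called (0 and 4 adjusted over the list alone; list adjusted p = 0.0108, and adjusted p = 0.677 with an estimated correlation). With the pigment epithelium score as a covariate the direction of this list turned to higher (median 0.03, adjusted p = 0.28), and that of the synapse list turned to lower (adjusted p = 0.948). Only 1 Cnga3 double knockout array, replicate 4 at 0.612, reached the score range of the Cngb3 double knockout (-0.101 to 0.682). These changes of direction therefore lean on that array and do not show that pigment epithelium accounts for the differences. The interferon list was higher, with H2-Q7 called (1 and 0; list adjusted p = 0.0334, and adjusted p = 0.875 with an estimated correlation). The amacrine list (0 called, 3 at an unadjusted p) gave adjusted p = 0.0439, and adjusted p = 0.554 with an estimated correlation. Over the 23 lists without a called member, 60 of 480 members passed at an unadjusted p.

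**Figure D3:**
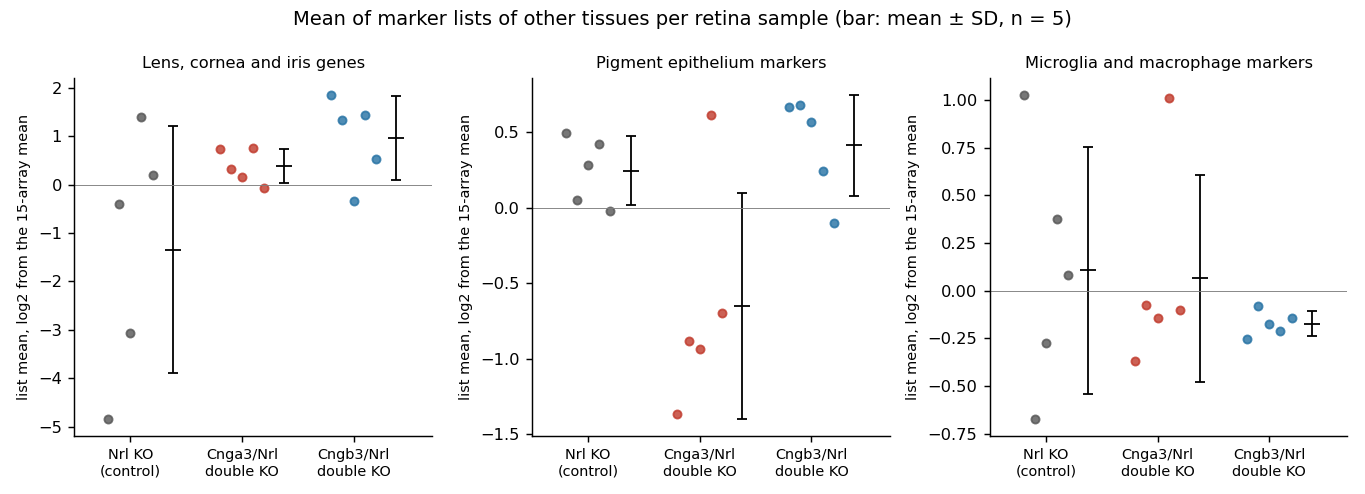
Mean score of the lens, pigment epithelium and microglia lists on each array by group, in log2 units relative to the mean over 15 arrays. The lens score is -4.85 in control replicate 1 and -3.07 in control replicate 3, and the pigment epithelium score averages -0.65 in the Cnga3 and 0.41 in the Cngb3 double knockout.

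Between the double knockouts 53 probes were called, 24 higher and 29 lower in the Cnga3 double knockout, for 20 and 23 genes, and 11 and 21 of these probes differed at least 2-fold. Median centring moved the share that was higher from 45.3 to 85.1%. Groups did not overlap for 4.93% of tested probes, where chance gives 0.794%. The count was 180, 23, 22 and 24 without Cnga3 double knockout replicates 1, 2, 3 and 5, and 21, 19, 21 and 23 without Cngb3 double knockout replicates 1, 2, 3 and 4.

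Some probes were called in both double knockouts. Guca1b, Pde6b, both Arr3 probes, Pdzph1, H2al1e, Riiad1 and Fscn2 fell and Drd4, Slc24a1, Atp2b1, Slc8a3 and Reep6 rose in both. In total 131 probes rose in both and 77 fell in both, and the shared control can add to these counts. The only probe called in opposite directions was that of Trf, which fell by 0.68 in the Cnga3 and rose by 0.79 in the Cngb3 double knockout. Without 1 library these calls ended in 8 and 7 of 10 fits. Fold changes correlated at 0.665 across probes, which are not independent replicates. The shared control alone gave 0.496 on average in simulated unchanged groups and 0.829 at most, so this correlation by itself does not show a shared response. The covariance was 0.0901 against 0.027 in those simulations, which had 0.0741 at most. The simulations shuffled residuals over all 15 arrays, while the control arrays agreed least with each other. Their lowest correlation was 0.9263, against 0.9401 in the Cnga3 and 0.9793 in the Cngb3 double knockout. The simulations can thus understate what the shared control adds, and the higher covariance does not show a shared response. The 5 control arrays were also split, with 2 for 1 contrast and 3 for the other. Over 20 such splits the correlation averaged 0.323 and ran from 0.145 to 0.512. On average 21.95 probes were higher (3 to 64) and 19 lower (11 to 49) in both, and 1.8 were called in opposite directions (0 to 10). With fewer controls per contrast the fold changes are also less precise. These splits therefore do not give how much the shared control alone adds. The shared count was 480, 80 and 130 without control replicates 1, 2 and 5. It was 134, 358 and 130 without Cnga3 double knockout replicates 2, 4 and 5. Without Cngb3 double knockout replicates 1, 2, 3 and 4 it was 77, 90, 103 and 91.

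**Figure D4:**
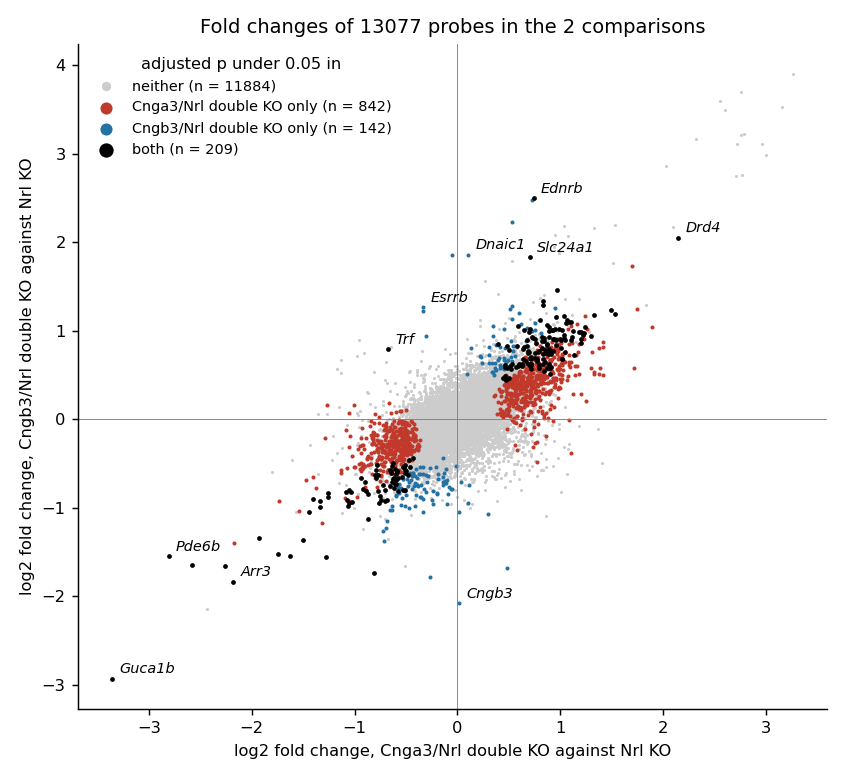
Log2 fold change of each of 13077 probes in the Cngb3 double knockout (vertical) against that in the Cnga3 double knockout (horizontal), both relative to the control and coloured by where the probe was called. Of the probes, 842 were called in the Cnga3 double knockout alone, 142 in the Cngb3 double knockout alone and 209 in both, with Guca1b, Pde6b and Arr3 low and Drd4 high in both.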

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

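The split counts and the lens ratio were predicted before their values were seen, while the tests of pigment epithelium genes and of control replicate 3 were chosen only after the result was seen. The lens-poor libraries left out for the lens ratio were picked after their lens scores were seen.

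The lens list score was low in 2 control libraries, at -4.85 in control replicate 1 and -3.07 in control replicate 3. Cryaa read 4.28 in control replicate 1 and 6.6 in control replicate 3 against at least 12.42 on the other arrays, and Crygs 5.64 and 9.31 against at least 14.1. Lens tissue carried along with the retinas of the other 13 arrays is a candidate cause of calls against the control, and chance is another. Without those 2 libraries, the log2 fold changes of the called probes were compared with the original ones. Their median ratio was 1.03 in the Cnga3 (quartiles 0.896 and 1.16) and 1.03 in the Cngb3 double knockout (0.942 and 1.15), with 0 sign changes. The called fold changes thus did not rest on those 2 libraries. This ratio cannot weigh lens tissue as a cause, since probes with widely spread controls are seldom called. Of the 24 lens, cornea and iris genes, 0 were called. Of 100 splits of the arrays only 1, the real one, gave as many calls in each comparison. The counts were 1051 against at most 232, 351 against at most 7, and 53 against at most 23 between the double knockouts. These values argue against chance as the source of the counts, but do not exclude it. Not every split was run, and a split that mixes the groups adds any real difference to the residual spread. Between the double knockouts the test is weaker, since the real grouping gave 19 to 180 calls without 1 library.

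Pigment epithelium genes were lower in the Cnga3 than in the Cngb3 double knockout, by a list median of -1.19. Scores of the Cnga3 double knockout were -1.37, -0.88, -0.94, 0.61 and -0.70, while the other 10 arrays lay between -0.10 and 0.68. Pigment epithelium carried along in dissection is a candidate explanation. The members moved together within groups, at a median correlation of 0.695 over the 12 members, above all 1000 random lists (random median 0.0121). An effect of the Cnga3 genotype on pigment epithelium RNA cannot be told apart from it. Markers of 1 tissue can move together under both, so this correlation does not decide between them. A second test counted the Cnga3 double knockout arrays above the median of the other 10. It found 1, which does not decide either. The bound for that test was first 1 array and was raised to 2 after the value was seen, since 1 library excludes nothing.

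Cngb3 was low in control replicate 3, at 7.32 where the Cngb3 double knockout averaged 6.95. The tables argue against a Cngb3 double knockout library with a wrong label. Over 368 probes other than Cngb3, called in a fit without this library, it had a median position of 0.137 (quartiles -0.313 and 0.704), where 0 is the mean of the other controls and 1 that of the Cngb3 double knockout. Left out in the same way, the 5 Cngb3 double knockout libraries lay at 0.691 to 0.986 and the other controls at 0.0343 to 0.653. Its Pde6b read 10.11 and its Arr3 12.91, where the highest Cngb3 double knockout values were 8.749 and 11.61. That fit was put in after a median of -0.19 had been seen over the probes called with the library included. A control animal that carried the sequence around Cngb3 from the knockout line may be another source, and it stays open, since the neighbours that differ were only 3 probes of 2 genes, with a median position of 0.0497. Necab1 lay at 0.883, near the knockout line like Cngb3 itself (0.852), and the probes of Dnaic1 at 0.0497 and -0.0253. The minimum of 3 genes for that test was set after the values were seen, and no biological explanation was tested.

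Of 219 groups of 5 values tested for a value far from the other 4, 21 had one, where chance gives about 11. Control replicate 3 had 10302 detected probes, where the other controls had 11926 to 12510. Cnga3 double knockout replicate 4 stood apart in 9 list scores. It was lower for cone genes (-0.419), cGMP and cAMP signalling (-0.25), synapse genes (-0.245) and sex-linked genes (-2.41). It was higher for oxidative stress (0.469), injury and gliosis (0.704), microglia (1.01), oxidative phosphorylation (0.268) and ribosomal proteins (0.249). Control replicate 2 was low for oxidative stress genes, at -0.157. Control replicate 3 was low for the interferon list (-0.763) and proteasome subunits (-0.186), and for Matr3 (5.17), Irf7 (4.73) and Pcp4 (4.92). Cnga3 double knockout replicate 2 was high for Irf7, at 8.11. Control replicate 1 was high for Miga1, at 6.17. Cngb3 double knockout replicate 5 was low for Cox6a2 (6.16) and Dnaic1 (9.69) and high for Nme7 (4.78).

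Trf was called in opposite directions in the double knockouts, and the difference between them was -1.47 (adjusted p = 0.00136). Without 1 library its call against the control ended in 8 of 10 fits in the Cnga3 (adjusted p of up to 0.0863) and in 7 of 10 in the Cngb3 double knockout (up to 0.101). The difference between the double knockouts stayed called in all 10 fits. Xist, which was not part of the comparisons, read 5.94 and 6.91 on its 2 probes in Cnga3 double knockout replicate 4 and 6.21 and 7.64 in control replicate 5. On the other arrays these probes read 4.3 to 4.6 and 4.4 to 5.25. The Y-linked Eif2s3y and Kdm5d were not detected on the same 2 arrays (Eif2s3y 4.4 and 4.425, against at least 9.028 elsewhere). Xist without Y-linked signal is the pattern of a female, and all other arrays showed the male pattern. The Cngb3 double knockout thus held no female array. Cnga3 double knockout replicate 4 is also the array that stood apart in the list scores above, and sex was not tested as a cause of that.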

How the results depend on the processing

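The alternatives that left out the lens-poor controls or used the lens or pigment epithelium score as a covariate were tests chosen only after the result was seen, and the others were planned. Of 230 named results 141 were called. Of these none reversed its direction under any alternative run on it, 66 stayed past the threshold under every alternative run on them and 75 lost the call under at least 1. Not every alternative was run on every named result, for example those for lens tissue only on named results against the control.

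The cause of the changes below was not tested, apart from those that follow by construction. A stricter threshold calls fewer probes, and a list loses its shift when its own mean is the covariate. The count of 1051 in the Cnga3 double knockout became 323 with only the 2 groups compared, 1880 with array weights, 232 at an adjusted p under 0.01 and 2001 with the pigment epithelium covariate. In the Cngb3 double knockout 351 became 230 with only the 2 groups, 1054 with array weights, 200 with the Xist covariate, 49 at an adjusted p under 0.01 and 849 without the lens-poor controls. Between the double knockouts 53 became 201 with median centring, 1170 with array weights, 122 with the replicate block, 17 at an adjusted p under 0.01 and 1094 with the pigment epithelium covariate. The 208 probes shared in direction became 84 with only 2 groups, 646 with array weights, 137 with the Xist covariate, 543 without the lens-poor controls and 333 with the lens covariate. Without the lens-poor controls 778 of the 1051 and 309 of the 351 calls were kept.

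The 5 lists called in the Cnga3 double knockout became 3 with only the 2 groups, 3 with the replicate block, 3 with the mean of all probes, 2 without the lens-poor controls and 0 with an estimated correlation. With the pigment epithelium covariate there were again 5, of which 2 were kept (endoplasmic reticulum stress and lens). The synapse and amacrine lists were lost (adjusted p = 0.696 and 0.14). The pigment epithelium list was lost by construction (adjusted p = 0.786), since its own mean is the covariate. At the preset correlation the microglia, injury and oxidative stress lists came in. In each of these, Cnga3 double knockout replicate 4 stood apart from its group (scores of 1.01, 0.704 and 0.469). The 2 lists of the Cngb3 double knockout became 1 without the lens-poor controls, 1 with the lens covariate, 4 with the pigment epithelium covariate and 0 with an estimated correlation. The 8 lists that differed between the double knockouts became 5 with probes detected on all 15 arrays, 5 with the mean of all probes and 0 with an estimated correlation. With the pigment epithelium covariate there were 6, of which only the interferon list was among the 8. Fits with this covariate lean on Cnga3 double knockout replicate 4, the only array of its group within the score range of the other groups. Without the lens-poor controls the lens (adjusted p = 0.024) and microglia lists (adjusted p = 0.0421) came in, and with the lens covariate the amacrine list was lost (adjusted p = 0.0708).

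Leaving out 1 library at a time gave 551 to 1229 calls in the Cnga3 and 130 to 828 in the Cngb3 double knockout, 19 to 180 between them, 77 to 480 shared, and 2 to 6, 2 to 4 and 4 to 9 lists. The lowest were without Cnga3 double knockout replicate 5 (551), Cngb3 double knockout replicate 1 (130) and Cngb3 double knockout replicate 2 (19).

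The labels do not say whether the replicate number pairs animals, and as a block it gave 1107, 387 and 122 calls. Of 15 pairs of arrays with the same number, residual correlations ran from -0.107 to 0.28, and 4 matched best with their own number. The slide alternative was not run, since no slide is given. Signal over background limits probes near the detection limit, whose folds are given as bounds.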

Other observations

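The tests of genes next to the targeted genes and those with the pigment epithelium covariate were chosen only after the result was seen.

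Of the lists of energy metabolism and protein turnover, none passed the list test, and some did with the pigment epithelium score as a covariate. These were oxidative phosphorylation in the Cngb3 double knockout (lower, adjusted p = 0.0133) and, higher in the Cnga3 than in the Cngb3 double knockout, oxidative phosphorylation (adjusted p = 0.00224), ribosomal proteins (adjusted p = 0.00854) and proteasome subunits (adjusted p = 0.0367). All used the preset correlation, and no estimated correlation was run with this covariate. Cnga3 double knockout replicate 4 stood apart for oxidative phosphorylation (0.268, others -0.115 to -0.0828) and ribosomal proteins (0.249, others -0.0887 to -0.076). It also had the highest pigment epithelium score of its group, at 0.612. In the Cnga3 double knockout, the hexokinase gene Hk2 fell by 0.95 (SE 0.196, adjusted p = 0.00933) and Hk1 rose by 0.79 (adjusted p = 0.0181) among 18 glycolysis genes (1 and 1 adjusted over the list alone). In the Cngb3 double knockout the glucose transporter gene Slc2a1 rose by 0.62 and 0 fell (1 and 0 adjusted over the list alone). Of 84 oxidative phosphorylation genes, 2 rose and 3 fell in the Cnga3 double knockout (1 and 3 adjusted over the list alone), with Atp5a1 up by 0.62 (adjusted p = 0.00873), Cox6c up by 0.71 and Atp5o, Atp5g1 and Ndufaf5 at -0.56, -0.55 and -0.50. Without Cngb3, Cox6a2 rose and Ndufaf5 (-0.58) and Cox6b2 (-0.71) fell (1 and 2 adjusted over the list alone). Of 34 proteasome subunits, Psmd6 (0.97) and Psma4 (0.60) rose and Psmd8 (-0.56) and Psmd13 (-0.41) fell in the Cnga3 double knockout (3 and 2 adjusted over the list alone), and limma called 0 in the Cngb3 double knockout (3 at an unadjusted p, 0 adjusted over the list alone). Of 61 ribosomal protein genes, Rps14 fell by 0.38 in the Cnga3 double knockout (0 adjusted over the list alone), and Rpl29 and Rps19bp1, which the prefix takes in, fell by 0.68 each in the Cngb3 double knockout (0 and 2 adjusted over the list alone). Calls of Slc2a1, Cox6c, Atp5o, Atp5g1, Ndufaf5, Cox6b2, Psma4, Psmd13, Rps14, Rpl29 and Rps19bp1 ended when some single libraries were left out, with adjusted p of up to 0.132 for Slc2a1 without Cngb3 double knockout replicate 4.

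Immediate early and clock genes gave few calls. Of 12 immediate early genes, the phosphatase gene Dusp6 fell by 0.54 in the Cnga3 double knockout (0 and 1 adjusted over the list alone; adjusted p = 0.0199, and 0.0514 without control replicate 2), and Jun fell by 0.83 in the Cngb3 double knockout (0 and 1 adjusted over the list alone; SE 0.15, adjusted p = 0.00979). Between the double knockouts limma called 0 of them, with 6 at an unadjusted p (4 higher and 1 lower adjusted over the list alone), and the list gave adjusted p = 0.0232, and adjusted p = 0.33 with an estimated correlation. Of 16 clock genes, Drd4 alone was called in either double knockout, at 2.15 and 2.05 (1 and 0, and 2 and 0, adjusted over the list alone). Of 16 cholesterol synthesis genes, Insig1 fell by 0.64 in the Cnga3 double knockout (0 and 1 adjusted over the list alone), while its 2 other probes pointed the opposite way and the call ended in 4 of 10 fits without 1 library (adjusted p of up to 0.072 without Cnga3 double knockout replicate 5). In the Cngb3 double knockout limma called 0 of them, with 4 at an unadjusted p (0 adjusted over the list alone; Msmo1 0.41, Pmvk 0.44). Of 3 sex-linked genes 0 were called and 0 passed at an unadjusted p (Eif2s3y 0.25 and 0.89, Kdm5d -0.07 and 0.48). These means depend on 2 arrays, since Eif2s3y was not detected in Cnga3 double knockout replicate 4 (4.4) and control replicate 5 (4.425) and read at least 9.028 on the others.

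Strain sequence that stayed linked to a targeted gene may change the level or the probe binding of its neighbours. Among the 100 tested genes nearest to Cnga3 in gene order, 14 were called in the Cnga3 double knockout, against 9.93% of the others (1-sided Fisher exact p = 0.121, odds ratio 1.48). This excess was not particular to that group. In the Cngb3 double knockout 6 of the same 100 were called, against 3.4% of the others (1-sided Fisher exact p = 0.129, odds ratio 1.81). Hspd1, Rims1 and Tfap2b, named in the Results, were among the neighbours of Cnga3 called in the Cnga3 double knockout. Of these, Hspd1 and Rims1 were also called in the Cngb3 double knockout. Among the 80 nearest to Cngb3, 3 were called in the Cngb3 double knockout, against 3.42% of the others (1-sided Fisher exact p = 0.519, odds ratio 1.1). These were Decr1 (-0.69), Dnaic1 (1.86) and Necab1 (-1.68). Between the double knockouts Dnaic1 and Necab1 were called among those 80 (odds ratio 5.75, 1-sided Fisher exact p = 0.0525). Of the 100 nearest to Cnga3, only 1, Arhgef4, was called there (odds ratio 2.15, 1-sided Fisher exact p = 0.379). In each gene's own double knockout the hypothesis stays open, since neither odds ratio was under 1 and neither test passed.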
